A study of Mus musculus with 4 samples.

How the data were processed

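Total RNA of hippocampi dissected at postnatal day 2 was measured on 4 Affymetrix arrays, 2 labelled control and 2 labelled Zbtb20 knockout. The labels do not say whether an array held 1 animal or a pool, or whether arrays of a group came from separate animals. The spread behind the p-values may therefore be partly technical. In the fit as designed it also holds the difference between the 2 scales described below, so its p-values do not measure variation between animals. The deposited values were signal intensities on a linear scale, made with MAS5 per the submitters' processing notes. No version, scaling target or background setting was given in the sources used here. Taken from the values, the trimmed mean (2% at each end) was 498 and 497 on the replicate 1 arrays and 158 and 156 on the replicate 2 arrays, the median signal was 142 and 130 against 73.8 and 75.8, and the lowest signal was 0.3 against 1. The replicate 1 values had 1 decimal, while 89.8% and 89.9% of the replicate 2 values had a second. The SD of log2 signal was 2.72 and 2.91 on the replicate 1 arrays and 1.68 and 1.65 on the replicate 2 arrays. The arrays with the same replicate number therefore shared their scale, and each scale held 1 array of each group. Whether the replicate 2 values went through a step beyond those of replicate 1 stays unknown. The number of arrays limits the precision of every comparison.

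Probe sets were named with the platform annotation. Of 45037 probe sets 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were named. Of the named probe sets, 34741 matched a RefSeq gene table by Entrez ID, which updated 0 symbols, and 18193 genes were represented. No probe positions and no genome build were given, so no coordinates are stated. Control probe sets numbered 0.

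Signals were transformed as log2(signal + 32.56), where the pseudocount was the 20th percentile of all values over the 4 arrays, so fold changes of dim genes are understated. Differences are on this scale. The authors' scaling was kept. Probe sets with a mean above the 40th percentile were kept (27022), and each gene was represented by its kept probe set with the highest mean, which gave 12581 genes. Probe sets of 1 gene over 2-fold apart in both directions occurred for 6 genes in pair 1 and 0 in pair 2. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend on all 4 arrays, knockout minus control, and Benjamini-Hochberg adjustment with a threshold of 0.05. The design had no covariate. The labels do not say that replicate numbers mark litters or days. After the data were seen, the scale of the values was taken as a processing batch that coincides with the replicate number, and a fit with it as a block and the values within each pair of arrays are given beside the fit as designed. Deviations of same-numbered arrays from their group means correlated at 0.826 across genes. The residual degrees of freedom were 2 without and 1 with the block. The prior degrees of freedom that eBayes estimated were infinite without and 5.96 with the block. Without the block each SE was thus the value of the mean-variance trend at that brightness, and not the gene's own spread.

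Before the data were examined, 22 gene lists were fixed: CA1 field, CA2 and CA3 fields, dentate gyrus, subiculum and retrosplenial cortex, deep and superficial cortical layers, medial pallium patterning and Wnt, Cajal-Retzius cells, GABAergic interneurons, astrocytes and radial glia, oligodendrocyte lineage, microglia, endothelium and pericytes, choroid plexus, meninges, thalamus, striatum, red blood cells, cell cycle, synapse and neuronal maturation, immediate early genes and sex-linked genes. The 20 lists with at least 4 measured members, the sex-linked list apart, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists, and with camera at an estimated correlation and fry. Lists of liver genes and of ependyma and motile cilia were added after the data were seen and are given as values. The percentile of a list's median within a pair is among 10000 random lists of the same size, drawn from 20 bins of mean expression.

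Genes were named by a rule fixed before the data were examined: up to 15 per direction past the threshold with both knockout values on one side of both control values, filled with those of smallest unadjusted p up to 5 per direction where fewer passed, the Zbtb20 probe sets, and up to 4 members of each list with the smallest unadjusted p. Genes over 2-fold apart in both pairs, and genes apart in the same direction, were named after their values were seen. The alternatives tried were quantile normalization, centring on the 75th percentile, a floor of 1 without a pseudocount, a pseudocount at the 40th percentile, no filter or one at the 60th percentile, the mean of a gene's probe sets, all probe sets, eBayes without trend or robust, the block, and leaving out each array. Scaling to 1 trimmed mean, and the block with either normalization, were added after the data were seen. The scripts were tested on simulated data for 12581 genes with 200 of them changed, by log2 1 or 2, alike in both pairs.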

Results

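Gene expression was measured in hippocampi of mouse pups at postnatal day 2. Tissue labelled as knockout of Zbtb20, which encodes a zinc finger transcription factor, was compared with tissue of littermates labelled as control, to find genes that depend on the factor during hippocampal development. Total RNA was hybridised to 4 Affymetrix arrays, 2 per group, and each array gave a signal for 45037 probe sets. The arrays came on 2 scales. The trimmed mean signal was 498 on the control and 497 on the knockout array of replicate 1, and 158 and 156 on the arrays of replicate 2. The Spearman correlation across probe sets was 0.926 between both replicate 1 arrays and 0.986 between both replicate 2 arrays, and lay between 0.818 and 0.832 for arrays of different replicate number. Differences are therefore also given within each pair of arrays on one scale, as the array labelled knockout minus the array labelled control, with pair 1 for the replicate 1 arrays and pair 2 for the replicate 2 arrays. A value within a pair sets 1 array against 1 array and carries no p-value.

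The targeted gene was examined first. Zbtb20 was represented by 9 probe sets, and 0 of them were lower in the array labelled knockout in both pairs. In pair 1, 3 probe sets were lower, and in pair 2, 2 were. The widest difference was at 1443471_at, where the ratio of labelled knockout to labelled control was 0.492 in pair 1 (signal 2412 against 4939) and 1.97 in pair 2 (592 against 284). For 1439128_at the ratio was 0.746 in pair 1 and 1.13 in pair 2, and for 1422064_a_at it was 1.06 and 1.51. With quantile normalization or with all arrays scaled to 1 trimmed mean, 1439278_at changed the sign of its pair 2 difference (log2 -0.01 as deposited), and no other Zbtb20 value changed sign. In limma's test at probe-set level 0 of the 9 probe sets passed an adjusted p of 0.05, with or without the replicate number as a block. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, so a probe set outside that part checks nothing. The Zbtb20 signal therefore did not settle the genotype labels, since 1443471_at was lower in the array labelled knockout in pair 1 and higher in pair 2. Directions below follow the labels as given.

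**Figure D1:**
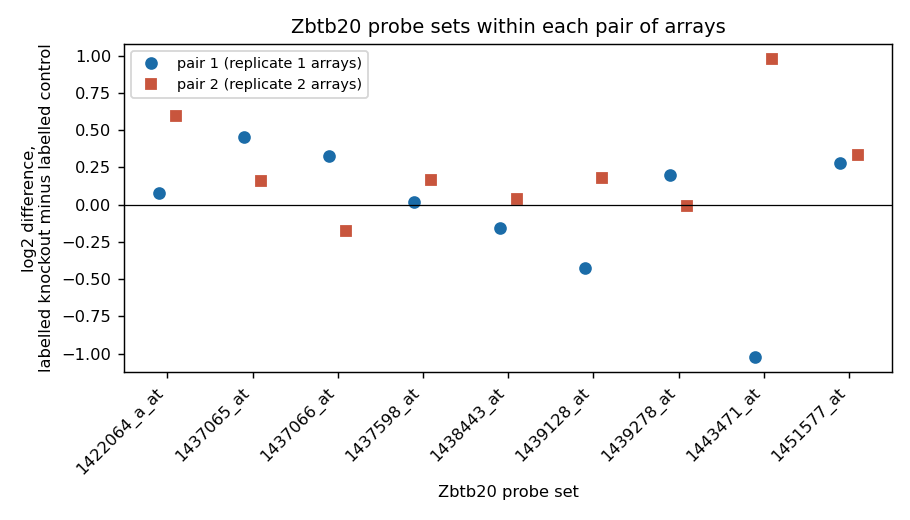
Log2 difference (array labelled knockout minus array labelled control, vertical axis) of each of the 9 Zbtb20 probe sets (horizontal axis) within pair 1 (circles) and pair 2 (squares), 1 array against 1 array for each point. Probe set 1443471_at lies at -1.02 in pair 1 and 0.98 in pair 2.

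The genes that were over 2-fold apart in both pairs went in opposite directions in the 2 pairs. Tshz3 and Tshz2, which encode teashirt zinc finger transcription factors, differed by log2 -2.20 and -1.91 in pair 1 and by 2.34 and 2.14 in pair 2. Nts, the precursor of the peptide neurotensin, differed by -1.60 and 2.15, and Nr4a2, an orphan nuclear receptor, by -1.61 and 1.97. Dio2, the deiodinase that activates thyroid hormone, differed by -1.54 and 1.60, Dcn, the matrix proteoglycan decorin, by -1.74 and 1.36, and Fosl2, a subunit of the AP-1 transcription factor, by -1.12 and 1.87. The reverse was seen for Scg2 (secretogranin II), at 1.92 in pair 1 and -1.88 in pair 2, for the transcription factor gene Zic4, at 1.25 and -2.07, for Lpl (lipoprotein lipase), at 1.73 and -1.42, for the guidance molecule gene Sema3c, at 2.05 and -1.38, and for the vasopressin receptor gene Avpr1a, at 1.95 and -1.40. These genes were chosen after their values were seen.

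Among 12581 genes, 38 were over 2-fold apart in both pairs in opposite directions, against 1.59 expected from independent lists of the same sizes, and 0 in the same direction, against 1.79 expected. Of the 38 genes, 22 were higher in the array labelled knockout in pair 1 and lower in pair 2, and 16 were lower in pair 1 and higher in pair 2. In pair 1 alone 188 genes were over 2-fold higher and 324 over 2-fold lower in the array labelled knockout, and in pair 2 alone 32 and 51. Of all genes tested, 53.5% had opposite signs in the 2 pairs. Across genes, which are not independent replicates, the differences of the pairs correlated with Pearson's r = -0.245 and Spearman's rho = -0.156.

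**Figure D2:**
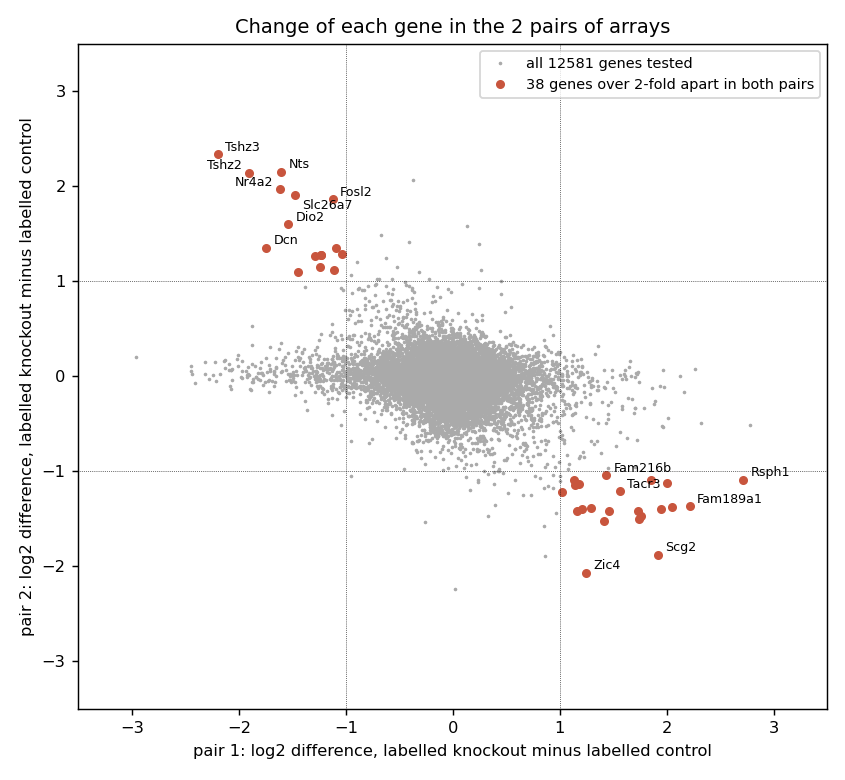
Log2 difference (array labelled knockout minus array labelled control) of each of the 12581 genes tested in pair 1 (horizontal axis) and pair 2 (vertical axis), with dotted lines at 2-fold. The 38 genes over 2-fold apart in both pairs (large points, some named) all lie in the 2 quadrants of opposite direction, 16 at upper left and 22 at lower right.

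Across all 4 arrays, 0 genes passed the test for a difference between the labelled groups. The limma fit as designed, without the replicate number, called 0 of 12581 genes at an adjusted p of 0.05 and found 0 at an unadjusted p under 0.05. With the replicate number as a block, limma also called 0 genes, 146 were under an unadjusted p of 0.05, and the smallest adjusted p was 0.9999. The genes that came closest in the fit as designed owed their values to pair 1. Their SE is that of the mean-variance trend, which is small for dim genes, and not the gene's own spread. All but Slitrk3 and Mat1a had a replicate 1 signal below the 20th percentile of that array (27.7 for control, 23.8 for knockout). Deup1 was at 13.3 on the control array, and Kdm5d at 2.3 on the knockout array. Toward higher signal in the arrays labelled knockout these were Deup1, which acts in centriole amplification of multiciliated cells, at log2 1.13 ± 0.62 (SE, n = 2 per group), followed by Kcnk3 (a two-pore potassium channel) at 1.02 ± 0.60, Slitrk3 at 0.997 ± 0.60, Vamp5 at 0.92 ± 0.59 and Pyroxd1 at 1.06 ± 0.69. Deup1 was at 2.77 in pair 1 and -0.51 in pair 2, Kcnk3 at 1.97 and 0.07, Slitrk3 at 2.16 and -0.17, Vamp5 at 1.94 and -0.10, and Pyroxd1 at 2.13 and 0.000516. Toward lower signal they were 4930413G21Rik at -1.15 ± 0.59, Creb3l3 (a liver-enriched transcription factor) at -1.11 ± 0.64, the Y-linked histone demethylase gene Kdm5d at -1.04 ± 0.60, Epn3 at -1.002 ± 0.58 and Mat1a (the liver form of methionine adenosyltransferase) at -1.10 ± 0.65. 4930413G21Rik was at -2.32 in pair 1 and 0.02 in pair 2, Creb3l3 at -2.24 and 0.01, Kdm5d at -2.22 and 0.15, Epn3 at -2.07 and 0.07, and Mat1a at -2.07 and -0.13. The fit as designed had little power, since the 2 scales entered its error. Of simulated genes changed alike in both pairs it recovered 0% at log2 1 and 12% at log2 2. The blocked fit recovered 84% and 100% of 100 genes each, with 14 false calls beside these among 12581 genes. The simulated noise was independent between the pairs, whereas the real differences of the pairs correlated at Pearson's r = -0.245. Simulated genes of like brightness also shared 1 SD, with no wider spread for single genes. The recovery of the blocked fit may thus be lower on the real arrays. Mgst1, at -0.95 in pair 1 and -1.05 in pair 2, had the smallest p of limma's blocked fit there (0.00048) and was not called. Its 0 calls therefore do not exclude a change of log2 1 alike in both pairs.

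Markers of the cortical regions next to the hippocampus were among the groups whose direction differed between pairs. Of 11 measured genes of the subiculum and retrosplenial cortex, 10 were lower in the array labelled knockout in pair 1 and higher in pair 2, and all 11 had opposite signs in the 2 pairs. The median of this list was log2 -0.51 in pair 1 and 0.29 in pair 2, at the 0 and 100 percentile of 10000 random lists matched on expression, a description of these arrays only. It held Nts and Nr4a2, with Tpbg at -0.38 and 0.17 and Ntng2 at -0.33 and 0.08. The list of deep cortical layers had a median of -0.20 and 0.78, and 7 of its 12 genes were lower in pair 1 and higher in pair 2, among them Zfpm2, a GATA cofactor, at -1.03 and 1.29. Tbr1, a transcription factor of early-born glutamatergic neurons, was at -0.01 and 0.89, Ccn2, a subplate marker, at -0.12 and 0.83, Nxph4 at -0.28 and -0.09, and Foxp2 went the other way, at 0.23 and -1.11. The 10 genes of superficial layers had medians of 0.01 and 0.12, with Inhba at 1.30 and -0.02, Mef2c at 0.26 and 1.12, Plxnd1 at 0.23 and 0.58 and Mdga1 at 0.51 and 0.01; the pair 1 median of this list turned sign with quantile normalization.

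Genes of the hippocampal fields had medians between -0.27 and 0.28. Among random lists the CA1 medians lay at percentiles 74.09 in pair 1 and 99.37 in pair 2. Those of the dentate gyrus lay at 98.88 and 59.54. The CA2 and CA3 medians lay at 92.13 and 0.05, and 7 of these 10 genes had opposite signs in the 2 pairs. The 9 genes of field CA1 had medians of 0.07 and 0.18, with the transcription factor gene Pou3f1 at 0.55 and 0.18, Fibcd1 at 0.24 and 0.06, Man1a at 0.73 and -0.33 and Mpped1 at 0.03 and 0.44. The 10 genes of CA2 and CA3 had medians of 0.16 and -0.27, with Nectin3, a synaptic adhesion molecule, at 1.70 and -0.96, Pcp4, a calmodulin regulator, at 0.86 and -1.89, Amigo2 at 0.76 and 0.01 and Bok at -0.15 and -0.48. The 8 dentate gyrus genes had medians of 0.28 and 0.01, with Prox1, the granule cell determinant, at 0.38 and 0.07, Tdo2 at -1.02 and -0.37, Lct at 0.52 and 0.11 and Lef1 at -0.49 and 0.06; the pair 2 median of this list turned sign with quantile normalization and with centring on the 75th percentile. Of 9 genes of medial pallium patterning and Wnt signalling, 7 were lower in pair 1 and higher in pair 2 (medians -0.31 and 0.12), with Wnt8b at -0.82 and 0.12, Emx1 at -0.29 and -0.19, Wnt5a at -0.07 and 0.42 and Fzd9 at -0.33 and 0.02.

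Lists of synaptic, interneuron and cell cycle genes had medians of opposite sign in the 2 pairs. Of 13 synaptic genes, 11 were higher in the array labelled knockout in pair 1 and lower in pair 2, with medians of 0.34 and -0.41 at the 100 and 0 percentile of random lists. Camk2a, a postsynaptic kinase, was at 1.16 and -1.42, Slc17a7, a vesicular glutamate transporter, at 1.02 and -0.41, Syn1 at 0.47 and -0.22 and Stx1a at 0.05 and -0.37. GABAergic interneuron genes had medians of 0.26 and -0.68, and 8 of 11 were higher in pair 1 and lower in pair 2, among them Gad2 at 1.14 and -0.16, the vesicular GABA transporter Slc32a1 at 0.17 and -0.93 and somatostatin (Sst) at 0.29 and -0.99, while Dlx2 was at -0.18 and -0.59. Cell cycle genes had medians of -0.24 and 0.16, and 10 of 14 were lower in pair 1 and higher in pair 2, including the mitotic kinesin Kif11 at -0.58 and 0.14, Tyms at -0.36 and 0.17 and the proliferation marker Mki67 at -0.08 and 0.42, with Cdk1 at -0.33 and -0.17. Across all 4 arrays none of these lists, nor those of the cortical layers and hippocampal fields, passed limma's camera test at an adjusted p of 0.05 in the fit as designed.

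**Figure D3:**
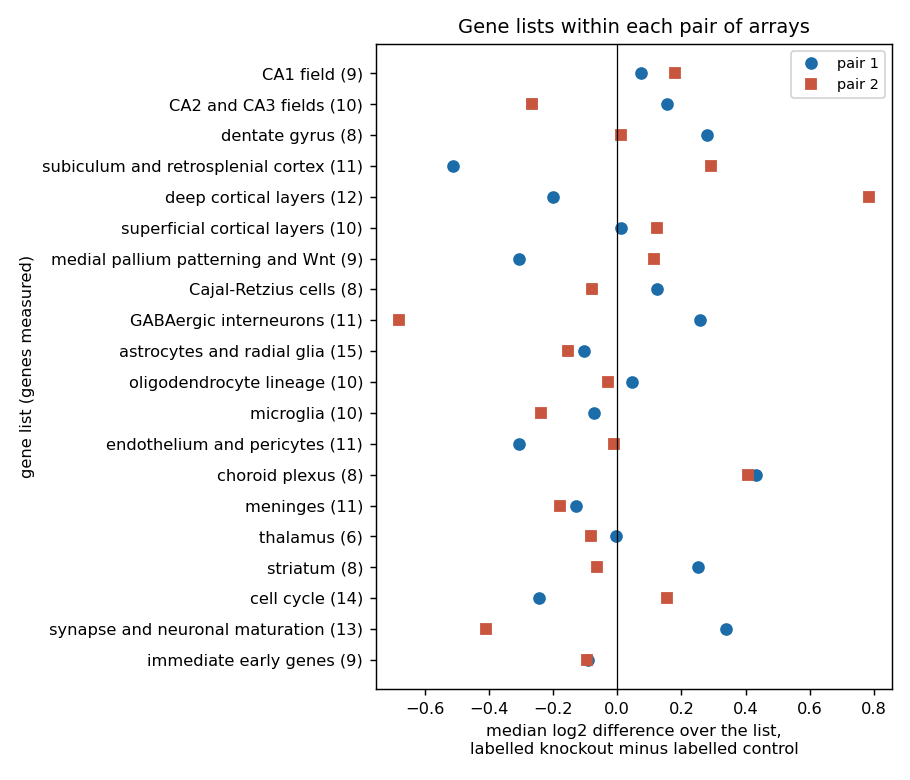
Median log2 difference (array labelled knockout minus array labelled control, horizontal axis) over each of 20 gene lists (vertical axis, genes measured in brackets) within pair 1 (circles) and pair 2 (squares). The subiculum and retrosplenial list lies at -0.51 and 0.29, the synapse list at 0.34 and -0.41, and the choroid plexus list at 0.43 and 0.41.

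Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, had medians on the higher side in both pairs (0.43 and 0.41). Of 8 measured members, 5 were higher in the array labelled knockout in both pairs: the folate receptor gene Folr1 at 0.91 and 0.53, the tight junction gene Cldn2 at 0.94 and 0.43, the potassium channel gene Kcnj13 at 0.85 and 0.38, the water channel gene Aqp1 at 0.44 and 0.48, and Ttr, the thyroid hormone carrier transthyretin, at 0.24 and 1.39. Otx2, the regulator of this epithelium, was at -0.06 and -0.62. On the control array of replicate 2, Folr1 (69.04), Kcnj13 (59.7), Cldn2 (33.99) and Aqp1 (32.89) lay below the array median of 73.79. On the knockout array they had 113.97, 87.71, 57.19 and 58.64, against a median of 75.83. The pair 2 values of these genes thus rest on dim signals, while Ttr was bright there (3505 and 9232). Of 20 lists tested with limma's camera at a preset correlation, this one passed (adjusted p = 0.00146). The call was lost with adjusted p = 0.98 with an estimated correlation, and fry gave an adjusted p of 0.982. It was also lost without control replicate 2 (adjusted p = 0.584) and without knockout replicate 1 (adjusted p = 0.719), and no member passed singly, with 0 of 8 over all genes and 0 of 8 adjusted over the list alone.

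Genes of other cell types had small medians or members in both directions. Among random lists the pair 2 median lay at percentile 0.07 for microglia (8 of 10 genes lower) and 0.18 for meninges (8 of 11 lower). The pair 1 medians of these 2 lists lay at 33.04 and 30.22. Of 15 genes of astrocytes and radial glia (medians -0.10 and -0.15), Hes1, a Notch target, was at -0.79 and -0.10, Pax6 at -1.13 and 0.47, Hes5 at -0.27 and -0.46 and Gfap at -0.10 and -0.41. The oligodendrocyte lineage had medians of 0.05 and -0.03, with Cldn11 at -0.80 and -0.14, Gpr17 at 0.86 and -0.04, Cnp at -0.38 and -0.70 and Mbp at -0.34 and -0.07. Microglial genes had medians of -0.07 and -0.24, with the adaptor Tyrobp at -0.53 and -0.54 and the complement gene C1qa at -0.37 and -0.70, while C1qc was at 0.05 and -0.85 and Aif1 at 0.70 and -0.28. Meningeal genes had medians of -0.13 and -0.18 (camera adjusted p = 0.0533, and adjusted p = 0.98 with an estimated correlation), with Slc6a13 at -1.47 and -0.20, Ogn at -1.41 and 0.24, Lum at -0.24 and -0.33 and Ptgds at 0.39 and -1.01. Endothelial and pericyte genes had medians of -0.31 and -0.01, the pair 2 value turning sign when arrays were scaled to 1 trimmed mean, with Tek at -0.83 and -0.00211, Cdh5 at -0.78 and -0.01, Abcc9 at -0.86 and 0.06 and Kcnj8 at -0.45 and -0.14.

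Cajal-Retzius cell genes had medians of 0.12 and -0.08, with Calb2 at 0.16 and -1.20, Cacna2d2 at 1.96 and -0.53, Ndnf at 0.24 and 0.24 and Ebf3 at -0.32 and -0.00486. Thalamic genes had medians of -0.00318 and -0.08, the pair 1 value turning sign with quantile normalization, with Tcf7l2 at -0.18 and -0.57, Prkcd at 0.37 and -0.05, Vav3 at -0.37 and 0.21 and Rora at -0.03 and -0.11. Striatal genes had medians of 0.25 and -0.06, with Drd1 at 0.90 and -0.03, Ppp1r1b at 0.84 and 0.06, Penk at 0.83 and 0.01 and Six3 at -0.31 and -0.36. Immediate early genes had medians of -0.09 and -0.09, with Btg2 at -0.46 and -0.29, Dusp1 at -0.63 and 0.10, Nr4a1 at -0.29 and 0.00425 and Jun at -0.20 and -0.09. Of the red blood cell list only Alas2, an enzyme of haem synthesis, was measured, at -0.28 and -0.31. Over the 22 lists fixed before the data were examined, limma called 0 members over all genes and 0 adjusted over the list alone, in the fit as designed and in the blocked fit.

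The replicate 1 arrays also carried transcripts of liver and of the X-inactivation gene Xist. Albumin (Alb) had a signal of 39309 on the control and 15195 on the knockout array of replicate 1, against 42.2 and 45.2 on those of replicate 2. Over 19 measured liver genes, a list added after the data were seen, the median percentile among probe sets was 90.4 and 71.8 on the replicate 1 arrays labelled control and knockout, and 18.0 and 18.2 on those of replicate 2. All 19 were lower in the array labelled knockout in pair 1 (median -1.82), among them the fibrinogen gene Fgb at -2.09 and Ambp at -2.28. In pair 2 the median was 0.03, with Fgb at -0.10 and Ambp at -0.02. Xist had a signal of 2994 and 4093 on the replicate 1 arrays and of 36.3 and 39.9 on those of replicate 2. The Y-linked gene Eif2s3y was at 304.5 on the control and 10.7 on the knockout array of replicate 1, and at 714 and 830.1 on those of replicate 2. Liver transcripts, Xist and Y-linked genes thus differed between the arrays of pair 1, beside each gene group whose pair 1 value is given above.

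**Figure D4:**
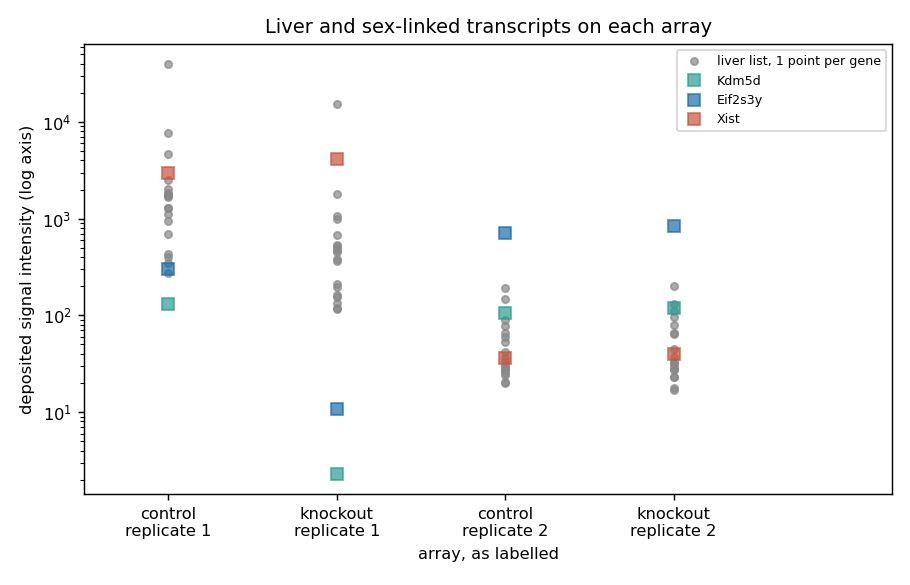
Deposited signal intensity (vertical log axis) of 19 liver genes (grey circles) and of Xist, Eif2s3y and Kdm5d (coloured squares) on each of the 4 arrays as labelled. Albumin, the highest circle on the replicate 1 arrays, lies at 39309 and 15195 there and at 42.2 and 45.2 on the replicate 2 arrays.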

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

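Scaling to 1 trimmed mean, the block combined with a normalization, and the counts within pairs were chosen after the data were seen. The count of genes called by limma (0) and of Zbtb20 probe sets called (0) was 0 under every alternative run, including the replicate block (0 and 0) and each left-out array (0 to 0), where the lone array of a group is assumed to vary like the other group. Without the block a repeated 0 carries little information, since that fit recovered 0% of simulated changes of log2 1. The blocked fit recovered 84% of them, but in the simulation genes of like brightness shared 1 SD and the noise was independent between the pairs. That rate therefore cannot be carried over to the real arrays. There Mgst1, at -0.95 and -1.05, had the smallest p of limma's blocked fit (0.00048) and was not called. The 0 of the blocked fit thus does not exclude changes of log2 1 alike in both pairs. The count of 38 genes over 2-fold apart in opposite directions ran from 27 to 55, except for 59 with no pseudocount, which also gave 1 gene in the same direction against 0; dim genes weigh more there by construction. The correlation of the pairs ran from -0.277 to -0.175. The 1 list called by camera became 0 with an estimated correlation and 0 with fry. The count was 3 with quantile normalization, 2 with centring on the 75th percentile, 2 with no pseudocount, 3 with the filter at the 60th percentile, 2 with the mean of probe sets, 4 with all probe sets, 2 with scaling to 1 trimmed mean, 3 with the replicate block and quantile normalization, and 1 with the replicate block alone. Leaving out 1 array gave 1 to 2. Besides choroid plexus the lists called in some of these were GABAergic interneurons, microglia, meninges and superficial cortical layers. Choroid plexus was among the lists called in each, except with an estimated correlation, fry, without control replicate 2 and without knockout replicate 1. The meninges list, not called as designed, had an adjusted p from 4.9e-06 (lower, without knockout replicate 1) to 0.861, and passed as higher without control replicate 1 (adjusted p = 0.0333); the cause of these changes was not tested, though leaving out an array leaves the groups unbalanced over the 2 scales. Of 1526 alternative values of 93 named genes, 133 lay on the other side of 0 and 0 passed. Signal over background limited what dim genes could show, since values near the pseudocount have compressed differences. The block alone changed no call.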

Other observations

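The tests in this part, the lists of liver and of motile cilia genes, and the genes apart in the same direction were chosen after the result was seen. Genes of ependyma and motile cilia had a median of log2 1.18 in pair 1 and -0.51 in pair 2, and 10 of 11 measured were higher in the array labelled knockout in pair 1 and lower in pair 2. Rsph1, a radial spoke component, was at 2.71 and -1.09, Dynlrb2, a dynein light chain, at 1.74 and -1.50, Cfap126 at 2.01 and -0.44, and Foxj1, the regulator of motile ciliogenesis, at 0.42 and -0.59.

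A few genes differed alike in both pairs, although none passed limma's test with the block. Mgst1, a membrane glutathione transferase, was at -0.95 and -1.05, Selenop, the selenium carrier, at -0.78 and -0.71, Glul, the glutamine synthetase of astrocytes, at -1.05 and -0.51, and Pcbd1 at -0.76 and -0.66. These genes are also active in liver, as is Itih3 at -0.95 and -0.68, and their pair 1 values stand beside a median of -1.82 over the liver genes there. On the higher side were Pip5k1b, a phosphoinositide kinase, at 0.54 and 0.73, Zfp386 at 0.49 and 0.68 and Kcne2, a potassium channel subunit, at 0.45 and 1.003. At log2 0.5, 10 genes differed alike in both pairs, against 59.9 expected from independent lists, and 219 differed in opposite directions, against 52.4 expected.

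The 2 pairs went in opposite directions. After quantile normalization over the 4 arrays 39 genes were over 2-fold apart in opposite directions, against 38 without it. The arrays of a pair already shared their scale, so this step could hardly turn a difference within a pair. It therefore cannot decide whether different processing of the pairs contributed. An exchange of the labels within 1 pair could give the pattern: with the labels of 1 pair turned, in either pair alike, the blocked limma fit called 91 genes against 0 as labelled (327 against 0 with quantile normalization), but any cause that sets the pairs apart would do the same, and 5 of the 9 Zbtb20 probe sets went in opposite directions while 4 were higher in both arrays labelled knockout. Unequal amounts of neighbouring cortex in the dissected tissue may also contribute, since subicular, retrosplenial and deep layer genes were among those that opposed. Over the superficial layer genes, however, the halved difference of pair 2 minus pair 1 had a median of only 0.11 against 0.46 for deep layers, with GABAergic genes at -0.55 and motile cilia genes at -1.02, and the hippocampal level of the superficial layer genes keeps this open. Neither these nor a difference between litters or animals, which was not tested, can be told apart with 4 arrays, and no array was relabelled.

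Liver transcripts on the replicate 1 arrays could come from RNA of liver in those samples. Of 19 liver genes, 18 ranked higher on both replicate 1 arrays than on both replicate 2 arrays. The list was added after the data were seen, so this count describes the signal and is no separate test of its source. On both replicate 2 arrays 4 of the 19 genes lay above the array median, so the hippocampus may express these itself. Although 0 of the 19 are on another list, those lists may still hold genes that liver expresses. Tdo2 of the dentate gyrus list had signals of 692.1 and 325 on the replicate 1 arrays labelled control and knockout. On those of replicate 2 it had 43.67 and 26.63. Higher expression of liver genes in the knockout itself was not seen as labelled. Their median was -1.82 in pair 1 and 0.0282 in pair 2, where the widest difference was 0.53 (Rbp4). On the replicate 2 arrays their median signal was 33.15 and 33.9, near the pseudocount of 32.56. Differences of that size of signal are compressed, so pair 2 cannot decide whether these genes change. Afp, another liver gene, had a signal of at most 112 on the control and 75.5 on the knockout array of replicate 1. Alb stood at 39309 and 15195 there. The age and origin of such liver RNA were not tested.

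On the control array of replicate 1 Xist and Y-linked genes were both present. The Eif2s3y signal there was at least 12.8 times that of the knockout array of replicate 1, whose dimmer signal was set at the 20th percentile of that array (23.8), with Xist high on both, which is consistent with RNA of both sexes in that sample, from a source that was not tested. No biological explanation of this signal was tested, and the sexes of the animals are not in the labels. By signal, both replicate 2 arrays had a male pattern, with Xist at 36.3 and 39.87 and Eif2s3y at 714 and 830.1. The knockout array of replicate 1 had a female one, with Xist at 4093, Eif2s3y at 10.7 and Kdm5d at 2.3. The replicate number thus also separated arrays with high Xist from arrays with low Xist.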
